A study of Caenorhabditis elegans with 6 samples.

How the data were processed

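Whole Caenorhabditis elegans of the wild-type strain N2 were grown to the L4 larval stage at 20 °C on Escherichia coli OP50, the usual laboratory food. They were then moved for 24 h at 25 °C to plates that held either OP50 or Pseudomonas aeruginosa PA14, a bacterium that infects the worm, per the labels' protocols. Total RNA from 3 OP50 control samples and 3 PA14 exposed samples was sequenced. The labels give replicate numbers and do not say that the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

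The authors deposited one table of FPKM values (read or fragment counts scaled by gene length and library total) with 46842 rows and 1 column per library. The submitters' processing notes name HISAT2 2.0.4, HTSeq 0.9.1 and DESeq 1.18.0 without a role or an order. The genome build was not given in the sources used here, and neither was the use of strand. Of the rows, 22742 were at 0 in all 6 libraries and 46364 had an identifier in the WBcel235 gene annotation, which gave gene names and coordinates. Another 116 rows carry names that the authors gave to loci of their own, and 54 of these were tested. Genes in families of near-identical copies, among them major sperm proteins, vitellogenins, collagens, cyp-35A and clc genes, are uncertain as single genes because reads can be shared between copies. The same holds for overlapping genes.

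The steps between low FPKM values gave the total behind each library, from 40032575 to 57237419 reads or read pairs. Each of the 13063 tested genes then came out at a whole number of reads in every library, within 0.02 of a read, with a median of 983 reads per tested gene. One read in a gene of 1 kb was worth between 0.0175 and 0.025 FPKM. The unit remains FPKM, so no count test was used as the main test, and the recovered reads served only as an added alternative. Within a group, no 2 libraries differed by as little as sampling noise, with a chi-square per gene between 62.3 and 265.3, so none was a copy of another. This does not show that they are separate cultures, and all 6 were kept as the separate samples that the labels list.

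FPKM values were tested as deposited, with no further scaling. Genes with a mean of at least 1 FPKM over all 6 libraries were tested, 12151 of them protein coding. The test was limma (version 3.58.1 in R 4.3.3) on log2(FPKM + 1), with a trend of variance on level and robust empirical Bayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene that passes is said here to be called, and the rises and falls counted in a list are called genes. Fold changes are PA14 exposed minus OP50 control on the log2(FPKM + 1) scale, which understates the change of low genes. Group levels are mean FPKM ± SD and fold changes are given ± SE.

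Gene lists were tested with camera at a preset inter-gene correlation of 0.01, for lists with at least 5 tested genes, beside camera with an estimated correlation and fry. There were 49 lists, of which 2 were too small. The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined, with 1 exception. The names in the list of mitochondrially encoded respiratory chain genes matched no gene name in the annotation. After the other results had been seen, that list was taken as the 12 protein-coding genes of the mitochondrial genome. It raised the lists tested from 46 to 47 and the lists called from 16 to 17. The rule for named genes took 3 kinds: the 10 largest called changes each way with a mean of at least 5 FPKM in the higher group and no overlap between groups, 25 fixed readout genes, and up to 3 called members of each list with at least 1 FPKM in the higher group. Genes named outside it are said to have been chosen after their values were seen.

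On simulated data with 3 libraries per group for this comparison and 12696 genes tested, the test recovered 40% of genes changed 1.5-fold, 85.4% of those changed 2-fold, 91.5% of those changed 4-fold and 100% of those changed 8-fold. It made 7 false calls among 160. Camera called 0 of 45 unchanged lists. That simulation has no correlation between genes, so it does not show how often camera calls lists whose genes vary together. Its spread was taken from the OP50 controls alone and shrunk towards the median over genes. In the real data, chi-square per gene was 109.5 to 265.3 between PA14 exposed libraries and 62.3 to 100.4 between controls. The simulated rates of recovery and of false calls may therefore not hold for these libraries. Alternatives covered the pseudocount, the filter, 4 scalings, the replicate number as a block, the moderation, library weights, a test against a 1.2-fold change, the threshold, and each library left out in turn. Added after the data were seen were voom on the recovered reads, a fit without the robust step, a covariate for sperm transcripts, a fit without replicate 2 of both groups, and the list count without the mitochondrial list. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.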

Results

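The transcriptomes of whole wild-type animals kept for 24 h on P. aeruginosa PA14 were compared with those of animals kept on E. coli OP50, with 3 libraries in each group. Library totals behind the FPKM values were 42461393, 40032575 and 57237419 reads or read pairs in the OP50 controls and 49910781, 45825709 and 51553257 in the PA14 exposed samples. Between 99.34% and 99.45% of each total lay in the tested genes. The totals thus appear to count reads assigned to genes rather than all reads sequenced. The comparison asks which genes differ in level between animals with and without exposure to the pathogen. The first principal component held 54.1% of the variance and separated the groups. The second held 19.3% and placed PA14 exposed 2 (38.5) and PA14 exposed 3 (-31.2) at opposite ends.

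In PA14 exposed animals, cld-1 rose from 0.146 ± 0.126 to 158 ± 31 FPKM (SD, n = 3 per group), a log2 fold change of 7.10 ± 0.18 (limma, adjusted p = 6.33e-05). Its neighbours dod-21 and dod-24 rose by log2 fold changes of 6.66 ± 0.27 and 4.58 ± 0.41. The 3 genes lie together on chromosome IV of WBcel235, cld-1 at 12935011 to 12936271, dod-21 at 12936738 to 12937988 and dod-24 at 12940106 to 12941354. B0024.4 rose from 3.19 ± 3.54 to 458 ± 178 FPKM and irg-5, an infection response gene, from 8.52 ± 3.82 to 318 ± 148 FPKM. The largest fall on the log2(FPKM + 1) scale was in acdh-1, an acyl-CoA dehydrogenase of propionate breakdown on chromosome I at 6497436 to 6499560, from 651 ± 151 to 3.23 ± 2.38 FPKM (log2 fold change -7.39 ± 0.40, adjusted p = 0.00116). The related acdh-2 had a log2 fold change of -4.64 ± 0.57, and pmp-5, an ABC transporter gene, fell from 32.3 ± 2.64 to 2.27 ± 0.666 FPKM. Of these genes, acdh-2 lost its call without OP50 control 1 (adjusted p = 0.065), and the others were called in each fit that left out 1 library.

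Of 13063 genes tested, 559 were called, 318 higher and 241 lower in PA14 exposed animals. Among them 264 were higher and 156 lower by at least 2-fold. All 559 had no overlap between the 3 exposed and the 3 control values, which a call on the same values nearly requires. Among all tested genes, 29.6% had no overlap, against 10% by chance. The number of calls fell to 92 without OP50 control 1, to 170 without OP50 control 3 and to 273 without PA14 exposed 3. Without PA14 exposed 1 it was 528, with 179 higher and 349 lower.

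**Figure D1:**
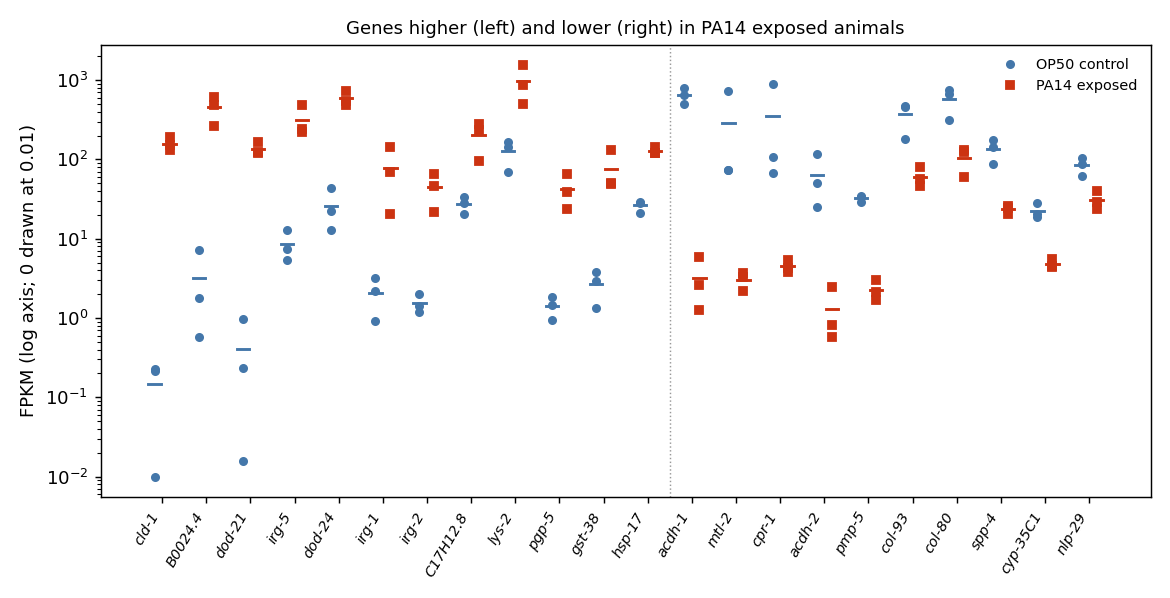
FPKM on a log axis for 12 genes higher and 10 genes lower in PA14 exposed animals, with 1 point per library and a bar at each group mean. The 3 exposed values lie apart from the 3 control values for each gene, while mtl-2 and cpr-1 each have 1 control library far above the other controls.

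**Figure D2:**
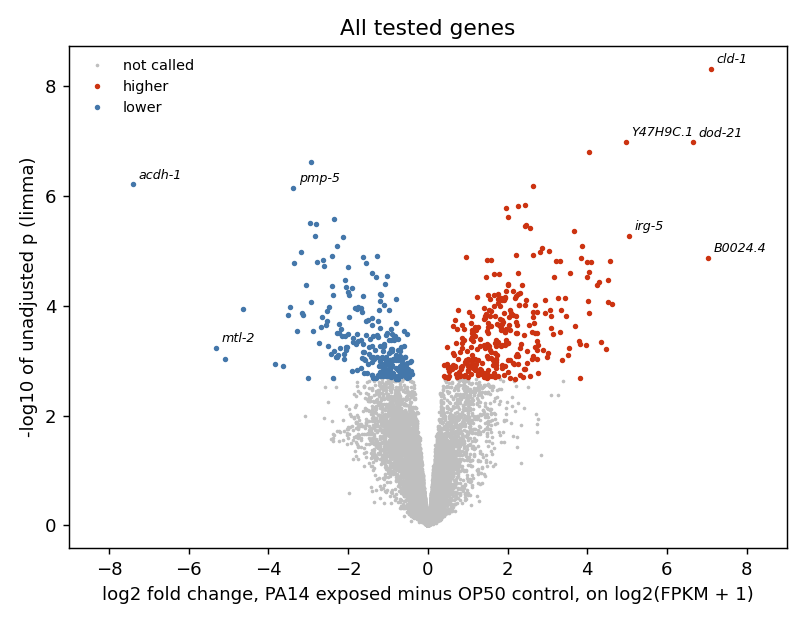
Log2 fold change on log2(FPKM + 1) against -log10 of the unadjusted limma p for the 13063 tested genes, with 318 called higher genes and 241 called lower genes in colour. The gene cld-1 lies at the far right at 7.10 and acdh-1 at the far left at -7.39.

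Other large rises were seen in Y47H9C.1 (log2 fold change 4.97 ± 0.21), C50F7.5 (4.53 ± 0.46), C49G7.12 (4.51 ± 0.53) and the claudin-like genes clc-12 (4.63 ± 0.55) and clc-19 (4.48 ± 0.73). Without OP50 control 1, clc-12 (adjusted p = 0.0592) and C49G7.12 (adjusted p = 0.0554) were not called, and clc-19 was called in 2 of the 6 fits that left out a library, with log2 fold changes from 3.91 to 5.11. Among the falls, E02H4.7 (-3.36 ± 0.30) and the cysteine protease cpr-5 (-3.51 ± 0.45) were called in all 6 of those fits. The C-type lectin clec-218 (-3.47 ± 0.42) was called in 5. The metallothionein mtl-2 (-5.31 ± 0.86) was at 291 ± 376 FPKM in controls, where OP50 control 3 alone stood at 725, and the protease cpr-1 (-5.10 ± 0.90) at 354 ± 464, where OP50 control 2 stood at 889. Without a library their log2 fold changes ranged from -5.86 to -4.22 and from -5.83 to -3.97, and they were called in 2 and 1 of the 6 fits. F42A10.7 (-3.84 ± 0.71) and spl-2 (-3.63 ± 0.68), a sphingosine phosphate lyase, were each called in 1 of the 6.

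Among genes of the immune response, 6 of 8 infection response genes were called higher and none lower, with log2 fold changes from -1.6 to 5.05 over the 8 (camera adjusted p = 2.93e-07, adjusted p = 0.784 with an estimated correlation). irg-2 rose from 1.54 ± 0.432 to 44.6 ± 21.9 FPKM, and irg-1 had a log2 fold change of 4.35 ± 0.68. Of 11 effectors of the p38 kinase pathway, 4 rose (camera adjusted p = 5.58e-06, adjusted p = 0.784 with an estimated correlation), among them C17H12.8 (2.74 ± 0.40) and clec-67 (2.65 ± 0.46). The p38 list shares irg-4 and irg-5 with the infection response list, clec-67 and clec-85 with the C-type lectins, and dod-22 with the dod genes. These list results are therefore not independent. Adjusted over the p38 list alone, 7 of the 11 passed. Of the other readouts on that list, sysm-1 went from 317 ± 84.9 to 931 ± 396 FPKM (adjusted p = 0.0568), K08D8.5 had a log2 fold change of 1.12 ± 0.40, irg-4 of 0.18 ± 0.28 and mul-1 of 0.60 ± 0.42, and none was called. With the 4 scalings, library weights, voom and the sperm covariate, 8 settings in all, sysm-1 was called (adjusted p from 0.0155 to 0.0462). Of 39 immune signalling genes, 6 rose (camera adjusted p = 0.00524, adjusted p = 0.92 with an estimated correlation), including the transcription factors cebp-1 (1.58 ± 0.28), nhr-8 (1.11 ± 0.16) and zip-2 (0.98 ± 0.18). The median of that list was only 0.1. Its mean level was 0.15, 0 and 0.13 in PA14 exposed 1 to 3 against -0.15, 0.04 and -0.17 in the controls (log2, relative to the mean of 6), so the groups overlapped. The kinase pmk-1 had a log2 fold change of -0.34 ± 0.17 and was not called. Called in all 6 fits that left out a library were irg-2 and irg-5. The genes irg-1, C17H12.8 and nhr-8 were called in 3, and clec-67, cebp-1 and zip-2 in 2.

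Of 9 dod genes, 5 rose (camera adjusted p = 2.02e-05, adjusted p = 0.784 with an estimated correlation), and dod-19 went from 98.6 ± 24.8 to 719 ± 152 FPKM. The pals genes had 2 rises among 11, pals-24 (2.46 ± 0.29) and pals-23 (2.27 ± 0.25), which neighbour each other on chromosome III (camera adjusted p = 0.00385, adjusted p = 0.92 with an estimated correlation). The median of the pals list was only 0.27. Its mean level was 0.35, 0.07 and 0.5 in PA14 exposed 1 to 3 against -0.46, -0.07 and -0.38 in the controls (log2, relative to the mean of 6). Of 83 F-box A genes, 10 rose and 1 fell, and 36 passed as higher adjusted over the list alone (camera adjusted p = 4.66e-11, adjusted p = 0.92 with an estimated correlation). Examples are fbxa-60 (2.31 ± 0.26) and fbxa-74 (2.31 ± 0.38), with fbxa-72 (-2.40 ± 0.21) going the other way. C-type lectins went both ways, with 12 of 87 higher and 8 lower (camera adjusted p = 0.114), from clec-4 (3.83 ± 0.78) to clec-218 (-3.47 ± 0.42), with clec-210 at -3.12 ± 0.40. The list was called at a mean of at least 5 FPKM (adjusted p = 0.0028). Among 12 lysozymes, lys-2 (2.88 ± 0.48) and lys-1 (1.66 ± 0.33) rose and ilys-5 (-2.38 ± 0.49) fell, while lys-7 was at 143 ± 62.2 and 190 ± 92.2 FPKM (camera adjusted p = 0.609). Antimicrobial peptides of the nlp and cnc families had 3 called lower among 20, cnc-3 (-2.0 ± 0.22), cnc-7 (-1.59 ± 0.31) and nlp-29 (-1.42 ± 0.25), and none called higher (camera adjusted p = 0.0439, adjusted p = 0.92 with an estimated correlation). That list was not called with a pseudocount of 0.1 (adjusted p = 0.0573), with no filter (0.0796) or at a mean of at least 5 FPKM (0.111). It was also not called without OP50 control 1 (0.0899), OP50 control 3 (0.126), PA14 exposed 1 (0.093) or PA14 exposed 2 (0.309). Its mean level was -0.33, -0.73 and 0.11 in PA14 exposed 1 to 3 against 0.43, -0.07 and 0.60 in the controls (log2, relative to the mean of 6). The saposin-like spp-4 (-2.41 ± 0.26) and spp-1 (-1.16 ± 0.22) fell out of 21 (camera adjusted p = 0.859), and fipr-11 (-1.99 ± 0.29) out of 18 fungus-induced peptides (camera adjusted p = 0.218, called without PA14 exposed 3 at 0.00786). Leaving out OP50 control 1 ended the calls of pals-23, pals-24, fbxa-60, cnc-3, spp-4 and clec-210, with adjusted p between 0.0526 and 0.0577. The genes lys-1, lys-2, ilys-5, spp-1 and cnc-7 were called in 1 of the 6 such fits, clec-4 in 0, nlp-29 in 2, fbxa-74 in 3 and fipr-11 in 5.

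**Figure D3:**
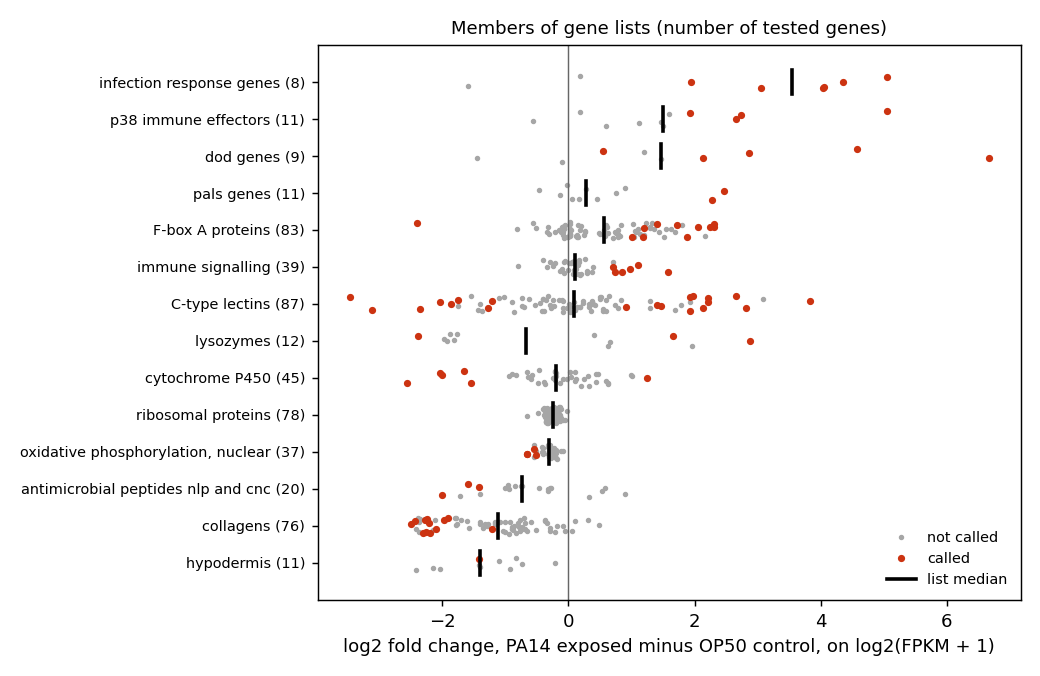
Log2 fold change on log2(FPKM + 1) of each tested gene in 14 gene lists, with called genes in red and the list median as a black bar. The median was 3.55 for infection response genes and -1.12 for collagens, and C-type lectins spread from -3.47 to 3.83.

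Collagens, the main proteins of the worm's cuticle, had 12 called lower and none called higher among 76 tested genes, with a median log2 fold change of -1.12 (camera adjusted p = 1.44e-14, adjusted p = 0.784 with an estimated correlation). Adjusted over the list alone, 45 passed as lower. The largest called falls were in col-93, from 372 ± 166 to 60.7 ± 17 FPKM, col-80 (-2.44 ± 0.42) and col-179 (-2.31 ± 0.40), which were called in 1, 2 and 2 of the 6 fits that left out a library. Hypodermis markers, 4 of 11 of them also in the collagen list, had a median of -1.40 with 1 called, nlp-29 (camera adjusted p = 1.04e-04, adjusted p = 0.92 with an estimated correlation). Adjusted over the list alone, 10 passed as lower. The gene nlp-29 is also in the list of antimicrobial peptides. As fixed, the hypodermis list also shares wrt-10 with seam and vulva, and elt-3 and lin-26 with the zygotic list, so these list results are not independent. Markers of seam and vulva had a median of -0.65 with 0 of 7 called (camera adjusted p = 0.0103, adjusted p = 0.92 with an estimated correlation). Of 20 body wall muscle genes, the troponin genes tni-1 (-1.62 ± 0.27) and tnt-3 (-1.21 ± 0.14) fell (camera adjusted p = 0.0175, adjusted p = 0.92 with an estimated correlation), called in 2 and 6 of those fits. The muscle list was not called without OP50 control 3 (adjusted p = 0.0853) or PA14 exposed 1 (0.155), and that of seam and vulva with library weights (0.073). The mean level of hypodermis markers was 0.07, -1.34 and -0.73 in PA14 exposed 1 to 3 against 0.46, 0.78 and 0.76 in the controls (log2, relative to the mean of 6), and that of seam and vulva markers -0.05, -0.99 and -0.30 against 0.28, 0.52 and 0.55. Without PA14 exposed 2, the lowest of the 6 in both, the medians were -1.04 and -0.59, and both lists were called. Sperm genes had 0 called of 38, and their mean level differed within groups, at -0.11, -1.25 and 0.93 in OP50 controls 1 to 3 and 0.52, -1.12 and 1.04 in PA14 exposed 1 to 3 (log2, relative to the mean of 6). Vitellogenins, the yolk proteins, took 8.62% of the library total in PA14 exposed 2 and between 3.62% and 4.95% in the other libraries, and none of 6 was called. Their member vit-2 was at 2600 ± 494 and 4110 ± 1760 FPKM.

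Among metabolic and detoxification genes, cytochrome P450 genes had 5 falls and 1 rise among 45 (camera adjusted p = 0.327), with falls in cyp-35A2 (-2.56 ± 0.35), cyp-35A3 (-2.04 ± 0.33) and cyp-35C1 (-2.0 ± 0.19). UDP-glucuronosyltransferases had 5 rises and 2 falls among 48 (camera adjusted p = 0.835), with ugt-31 at 3.08 ± 0.40, ugt-17 at -2.79 ± 0.25 and ugt-22 at -2.61 ± 0.24. The glutathione transferase gst-38 rose from 2.67 ± 1.25 to 76.2 ± 46.3 FPKM and gst-20 by 1.21 ± 0.17 (2 of 37, camera adjusted p = 0.13). The transferase list was called at a mean of at least 5 FPKM (0.0119) and without OP50 control 3 (0.0189) or PA14 exposed 1 (0.0138). The ABC exporter pgp-5 rose by 4.09 ± 0.37, and pgp-1 had a log2 fold change of -1.08 ± 0.21 (camera adjusted p = 0.619). Of 54 lipase and beta-oxidation genes, 5 fell and 1 rose, among them ech-6 (-1.62 ± 0.14) (camera adjusted p = 0.744). The desaturase genes fat-5 (-1.5 ± 0.28) and fat-7 (1.00 ± 0.18) went opposite ways, and elo-9 fell by 1.12 on the log2 scale (camera adjusted p = 0.739). The lipid binding gene lbp-8 had a log2 fold change of -2.93 ± 0.34 (camera adjusted p = 0.619). Nuclear-encoded genes of oxidative phosphorylation had 4 falls among 37 and a median of -0.31 (camera adjusted p = 2.24e-07, adjusted p = 0.784 with an estimated correlation), with gas-1, ucr-2.2 and asb-2 between -0.65 and -0.55. The 12 mitochondrially encoded ones had a median of -0.58 and 0 called (camera adjusted p = 0.0424, adjusted p = 0.92 with an estimated correlation). Their mean level was -0.48, -0.61 and 0.36 in PA14 exposed 1 to 3, against 0.01, 0.29 and 0.44 in the controls (log2, relative to the mean of 6). They were not called without OP50 control 2 (0.08), OP50 control 3 (0.104), PA14 exposed 1 (0.29), PA14 exposed 2 (0.174) or replicate 2 in both groups (0.22). Ribosomal protein genes had 0 of 78 called and a median of -0.24 (camera adjusted p = 1.04e-04, adjusted p = 0.92 with an estimated correlation). With quantile normalization the median was -0.09 and the list was not called (0.0831). Their mean level was -0.11, -0.42 and 0.16 in PA14 exposed 1 to 3, against 0.06, 0.07 and 0.24 in the controls, and without PA14 exposed 2 the median was -0.11. Called in all 6 fits that left out a library were cyp-35C1, ugt-17, ugt-22, gst-38, pgp-5 and ech-6. In 5 of them lbp-8 was called, in 4 ugt-31, cyp-35A2 and gst-20, in 2 cyp-35A3 and gas-1, in 1 fat-5, fat-7, elo-9, asb-2 and pgp-1, and in 0 ucr-2.2.

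Among stress readouts, the small heat shock gene hsp-17 rose from 26.2 ± 4.28 to 129 ± 13.1 FPKM and was called in all 6 fits that left out a library. hsp-43 (-0.94 ± 0.18) and sod-1 (-0.57 ± 0.10) fell and were called in 1 and 2 of those fits. The log2 fold change was 0.13 ± 0.10 for hsp-4, -0.12 ± 0.17 for hsp-6, 1.48 ± 0.72 for hsp-16.2, -1.21 ± 0.54 for gst-4 and 0.19 ± 0.26 for sod-3. It was -2.60 ± 0.75 for fmo-2, -0.35 ± 0.19 for sqrd-1, 0.43 ± 0.41 for cysl-2, -1.41 ± 0.69 for mtl-1, -1.11 ± 0.25 for ftn-1 and -0.25 ± 0.67 for clec-60, and none of these 11 was called. With the 4 scalings and library weights ftn-1 was called (adjusted p from 0.0329 to 0.0472). Lists for heat shock (adjusted p = 0.0957), oxidative stress (0.188), the mitochondrial (0.542) and endoplasmic reticulum (0.542) unfolded protein responses, hypoxia and sulfide (0.82), iron and metal (0.859), daf-16 targets (0.619) and flavin monooxygenases (0.315) were not called by camera. That of heat shock was called with no filter (0.0209) and without OP50 control 1 (0.0196) or PA14 exposed 3 (0.00262). In the metal list cdr-4 (1.5 ± 0.29) and cdr-2 (1.23 ± 0.20) rose, called in 0 and 2 of those fits.

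Of the remaining lists, oocyte and maternal genes (median 0.12, camera adjusted p = 0.00532) and autophagy genes (0.13, camera adjusted p = 0.0359) were called up, and zygotic embryonic genes (-0.34, camera adjusted p = 0.0359) down. Each had adjusted p = 0.92 with an estimated correlation, and the 1 called gene among them, glh-1 of the maternal list, fell by 0.47 on the log2 scale, against its list's direction. The mean level of oocyte genes was 0, 0.18 and -0.05 in PA14 exposed 1 to 3 against -0.02, -0.04 and -0.07 in the controls (log2, relative to the mean of 6), and the list was not called without PA14 exposed 2 (adjusted p = 0.327), without replicate 2 in both groups (0.439) or with library weights (0.0741). That of autophagy genes was 0.25, -0.13 and 0.08 against -0.04, -0.02 and -0.14, and the list was not called without OP50 control 3 (0.128) or PA14 exposed 1 (0.243). Zygotic genes were at 0.03, -0.64 and -0.05 against 0.22, 0.06 and 0.38, and were not called without OP50 control 1 (0.0564) or OP50 control 3 (0.195), or with no filter (0.088). With median-of-ratios scaling the medians of the oocyte and autophagy lists were both 0.20. Without PA14 exposed 2 the oocyte median was 0.06 and the zygotic one -0.11, and without OP50 controls 2 or 3 the zygotic one was -0.58 or -0.20. The autophagy median was 0.04 without PA14 exposed 1 and 0.07 without OP50 control 3 or PA14 exposed 3. Camera did not call proteases (adjusted p = 0.182), of which cpr-3 had a log2 fold change of 4.01 ± 0.47, the proteasome (0.542), insulin-like (0.496) or FMRFamide-like peptides (0.13), sperm genes (0.123), vitellogenins (0.842) or fatty acid binding proteins (0.619). Of these, sperm genes were called with the replicate number as a block (3.35e-06), with library weights (0.0382) and without OP50 control 3 (9.57e-05) or PA14 exposed 2 (7.28e-04). FMRFamide-like peptides were called with quantile normalization (0.0377) and without PA14 exposed 2 (7.28e-04) or replicate 2 in both groups (0.00125). Proteases were called without OP50 control 2 (0.0163) or replicate 2 in both groups (0.047). In the main fit, camera with an estimated correlation gave each of these lists adjusted p = 0.92. That correlation was 0.807 for sperm genes, 0.753 for FMRFamide-like peptides and 0.117 for proteases. Camera did not call markers of intestine (0.496), pharynx (0.82), neurons (0.82), the excretory cell (0.68) or gonad sheath and spermatheca (0.786). The median, mean and camera direction did not share a sign for lysozymes, saposin-like proteins, UDP-glucuronosyltransferases, the endoplasmic reticulum response, daf-16 targets, vitellogenins, the proteasome, proteases and insulin-like peptides. The same held for markers of intestine, neurons, the excretory cell and gonad sheath and spermatheca, and none of these lists was called. Thaumatin-like genes (2 tested) and coelomocyte markers (4 tested) were too few for a test, and none was called. The intestine list had 3 rises and 2 falls among 18, the falls being mtl-2 and cpr-1, and the protease list 2 rises and 3 falls among 21. Other called genes in these lists included ins-12 (-2.15 ± 0.32), flp-6 (-0.67 ± 0.11), ifc-2 (1.52 ± 0.21), aqp-8 (-1.08 ± 0.22) and fos-1 (0.83 ± 0.15). Of the 6 fits that left out a library, 5 called cpr-3, 4 called ins-12 and ifc-2, 3 called flp-6, and 1 called aqp-8, fos-1 and glh-1.

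In all, camera called 17 of 47 lists, 8 up and 9 down. With an estimated correlation, 0 of the 47 were called. That setting asks more of lists whose genes vary together, and it also tests on the few residual degrees of freedom of 6 libraries. Its adjusted p-values therefore do not reflect the correlation between genes alone. The fry test called 3, the infection response, dod and collagen lists. The 9 other ways to split the 6 libraries 3 against 3, each of which mixes the groups, gave from 7 to 20 lists by camera, with a median of 13. A mixed split still holds part of the group difference, so these counts are not a rate of false calls. The list calls by camera are to be read with caution. Of 79 named genes that were called, 22 were called in all 6 fits that left out a library.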

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

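The fits of voom on recovered reads, without the robust step, with the sperm covariate, without replicate 2 of both groups, and without the mitochondrial list were chosen after the data were seen. No called gene changed sign in any alternative that tested it. Against 559 calls (318 higher and 241 lower, 264 and 156 by 2-fold) and 17 lists, the settings below moved the total or one of these counts by over 1.5 times, and the cause was not tested beyond what each construction shows. With an adjusted p threshold of 0.01 there were 75 calls, 46 higher and 29 lower, 45 and 29 of them by 2-fold, and 11 lists. With no filter on low values (24100 genes tested) there were 197 calls, 128 higher and 69 lower, about 1.2e+02 and 64 by 2-fold. Against a 1.2-fold change there were 304, 196 higher and 108 lower, with 103 lower by 2-fold. Library weights gave 1987 calls, 1068 higher and 919 lower, 542 and 303 by 2-fold, with PA14 exposed 1 weighted 3.68 and PA14 exposed 2 0.269. Quantile normalization gave 864, 519 higher, 398 by 2-fold. Median-of-ratios scaling gave 493 higher, with a total of 784, under 1.5 times. Voom with median-of-ratios sizes gave 871, 522 higher, 403 by 2-fold. The sperm covariate gave 395 lower of 738 calls. Without replicate 2 in both groups, 485 were higher, 433 by 2-fold, of 663 calls.

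The replicate number as a block gave 207 calls, 102 higher and 105 lower, 91 and 80 by 2-fold. Deviations of same-numbered libraries correlated at 0.00, 0.10 and 0.29, and not every library correlated best with its own number, so the numbers were not taken as pairs. Of the 559 calls, 180 were also called with the block, which leaves 2 residual degrees of freedom.

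Leaving out each library in turn gave from 92 to 557 calls, from 55 to 390 higher, from 37 to 349 lower, from 54 to 320 higher by 2-fold, from 35 to 309 lower by 2-fold, and from 14 to 19 lists. The counts of 92, 170 and 273 came without OP50 control 1, OP50 control 3 and PA14 exposed 3, and without PA14 exposed 1 only 164 were higher by 2-fold and 309 lower by 2-fold. An estimated inter-gene correlation called 0 of 47 lists and fry 3, against 17 by camera, with 2919 genes at an unadjusted p under 0.05.

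Signs changed in 7 values of genes that were not called. For clec-60 (-0.25) the log2 fold change was 0.25 with a pseudocount of 0.1, 0.36 with library weights, and 0.96 and 1.06 with voom. Without PA14 exposed 3, irg-4 was at -0.14, hsp-6 at 0.04 and sod-3 at -0.07, and over all 6 libraries left out in turn they ranged from -0.14 to 0.43, from -0.27 to 0.04 and from -0.07 to 0.37. Of the other values of named genes, 1853 kept their side of the threshold, 444 lost a call and 13 gained one, and of list values 1062, 47 and 17. List medians that changed sign with the scaling were those of UDP-glucuronosyltransferases, lipases and beta-oxidation, fatty acid binding proteins, intestine, neurons, and gonad sheath and spermatheca. The count tests planned for a table of counts were not run, since the values are FPKM.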

Other observations

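The enrichment of gene classes, the tests on shunt, methionine cycle and collagen genes, and the counts over other splits were chosen after the results were seen, unlike the block fit, the fit without PA14 exposed 2 and the main calls, and the outcome expected of each weighed explanation was written down after its test had been run. Gene classes, taken as the letters before the hyphen of a gene name, were tested for enrichment among the calls by a one-sided Fisher's exact test over 116 classes with at least 10 tested members, against all 13063 tested genes. Of 232 tests, 9 passed Benjamini-Hochberg adjustment, and genes of a class are not independent. The strongest was nspg, a nematode-specific peptide family, with 7 of 11 higher (0.268 expected, adjusted p = 3.34e-07), led by nspg-7.2 (log2 fold change 3.58) and nspg-10 (1.97). Claudin-like clc genes had 4 of 20 higher (adjusted p = 0.0354), with clc-11 (3.36) and clc-1 (2.75) beside clc-12 and clc-19. The other 7 were col (12 of 68 lower), clec (12 of 87 higher and 8 lower), fbxa (10 of 83 higher), and, lower, acdh (3 of 10), alh (3 of 12) and cyp (5 of 45). The galectin class lec had 3 of 12 higher, lec-6, lec-8 and lec-10, and did not pass (adjusted p = 0.062).

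Of 5 tested genes of the propionate shunt, a route that breaks down propionate without vitamin B12, 4 were called lower in PA14 exposed animals. These genes were picked after acdh-1 was seen, and no list test was run on them. Beside acdh-1, hphd-1 went from 159 ± 31.2 to 21.8 ± 5.81 FPKM (SD, n = 3; limma, adjusted p = 0.00326), ech-6 had a log2 fold change of -1.62 and hach-1 of -1.24, and alh-8 (-0.73, adjusted p = 0.0523) was not called. The receptor genes nhr-114 (-2.37) and nhr-68 (-1.40) and the S-adenosylmethionine synthase gene sams-1 (-2.35) also fell, while the other receptor gene tested, nhr-10 (-0.18, adjusted p = 0.498), was not called. A general fall of lipid oxidation genes is argued against, since the other 52 genes of that list, acdh-2 (-4.64) among them, had a median of -0.03 with quartiles of -0.33 and 0.16, against -1.62 for the shunt. More vitamin B12 in the PA14 food is a candidate explanation. The 8 methionine cycle genes tested had a median of -0.42 with 2 called, sams-3 (-0.41) and the sams-1 already named. All 8 had their 3 exposed values below the 3 control values. The same held for 2 of the 5 genes of the vitamin B12-dependent route, with a median of -0.08 and 0 called, against 18.8% of all tested genes and 5% by chance in that direction. Food and infection changed together in this design, so they cannot be told apart.

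The lower collagens kept their direction in 3 checks, on gene length, on the sperm level and without PA14 exposed 2. With the trend of fold change on gene length removed, the median was -1.03 against -1.12 before. The bootstrap 95% interval, -1.24 to -0.81, resampled the collagen genes and not the libraries, so it leaves out the spread between samples. Medians of all tested genes in 5 bins of length ran from -0.08 to 0.01. There was thus little trend on length to remove, and such a trend could account for little of the fall. With the sperm level in the same model, the group difference in mean collagen level was -1.26 ± 0.14 against -1.21 ± 0.20 without it. Sperm transcripts read 1 aspect of stage, but their level varied mostly within groups. It was at -0.11, -1.25 and 0.93 in OP50 controls 1 to 3 and 0.52, -1.12 and 1.04 in PA14 exposed 1 to 3. Such a covariate could remove little of a group difference, so this fit does not decide on stage. Without PA14 exposed 2 the median was -0.92. A lower collagen level in exposed animals may be biological, as a hypothesis, with stage, food and infection all open and not told apart here.

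Libraries with the same replicate number had like levels of some transcripts. The mitochondrial ribosomal RNA gene MTCE.33 was at 53.9 and 52.5 FPKM in both libraries numbered 1, at 1.71 and 0.252 in those numbered 2 and at 75.4 and 70 in those numbered 3. The share of the library total in ribosomal RNA was 0.217% and 0.379%, 0.034% and 0.02%, and 0.054% and 0.056% in the same order. Libraries with 1 number prepared together could give this, but a fit with the number as a block called 207 genes and leaves 2 residual degrees of freedom, so it does not decide.

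The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The other 9 mix the groups, which adds the group difference to the spread, so few gene calls were expected in them. For genes called, 1 of the 10 splits, the real one, gave as many as 559, and the highest of the others was 0, with up to 993 genes at an unadjusted p under 0.05 by limma against 2919. For calls of at least 2-fold the count was likewise 1 split, with 420 against 0. For gene lists called by camera, 2 of the 10 splits gave as many as 17, and the other 9 gave from 7 to 20, with a median of 13. Part of the group difference stays in a mixed split, so these list counts are not a rate of false calls. The split with 20 set OP50 controls 1 and 3 and PA14 exposed 1 against the rest.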
